A study of Homo sapiens with 2 samples.

How the data were processed

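RNA from HCT116 cells, a human colorectal carcinoma cell line labelled here as p53+/+, was measured on 2 Illumina bead arrays, 1 for cells given vehicle and 1 for cells given the RAF kinase inhibitor SB590885 at 10 nM. Per the labels' protocols, RNA was extracted with a column kit and amplified into biotinylated cRNA with the Ambion MessageAmp kit. The time of treatment, the array software and the normalization are not given in the sources used here. Each condition had 1 array, so no replicate checks any difference, and no test across samples or p-value for a difference was computed.

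The authors deposited 3 tables of intensity values on a linear scale for 47318 probes, and all 3 hold 1 set of measurements. The intensities in the authors' normalized table equal those of the series matrix, with a largest difference of 0. Every intensity in the table deposited as non-normalized is 1.025 times the normalized intensity. The detection p-values in that deposited table were multiplied by 1.025 too and reach 1.025, so it holds no raw signal. It was used for these checks and for the alternative without background correction. In the deposited normalized table the detection p-values, given per probe and array, run up to 1 in steps of which 770 make 1 unit. They fall steadily with intensity on both arrays. The sorted intensities of the 2 arrays differ by at most 0.129 units, as after quantile normalization. The lowest intensity is 90.7, and a detection p of 0.5 corresponds to about 112.5, so background was left in the values. This compresses ratios, most of all for dim genes.

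The setting fixed before the data were examined was limma's neqc on raw signals, with the authors' normalized values as the fallback if no raw signals were usable. The fallback applied. The values reported are therefore log2 ratios of the deposited normalized intensities, SB590885 over vehicle, and neqc (offset 16, negative controls inferred from the detection p) applied to the same table is given as the background-corrected alternative. These corrected values start from already normalized intensities.

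Probes were named through a table of platform annotation, in which 30119 of the 47318 probes were listed. Of these, 30111 had 1 gene and 8 had several and were left unnamed. The annotation gave 20045 genes. Symbols were updated through the Entrez identifier for 30072 probes with RefSeq's GRCh38.p14 annotation, and 39 kept the older name. The array files name no genome build, so that annotation was used only for names, chromosomes and the order of neighbouring genes. Some genes on the lists fixed beforehand, among them some of those always to be named, have no named probe here and are not analysed here. Of 753 list entries, 695 had a named probe. A gene counted as detected with a detection p under 0.01 on at least 1 array, which 10430 genes met. Its value was that of its detected probe with the highest mean log2 intensity. A gene not detected on 1 array has only a bound there. Its fold was computed against the higher of its own intensity and the lowest detected intensity on that array (132.2 for vehicle, 129.8 for SB590885), and is written as "at least". Genes were counted as different by a rule of size, 2-fold or more, with 1.5-fold as an alternative.

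For each of 38 gene lists fixed before the data were examined, the median log2 ratio of the detected members was set against 10000 random lists of the same size, matched on mean expression in 10 bins. The percentile describes these 2 arrays and is not a p-value. Lists with under 5 detected members were not ranked, which left 34. A list is said to stand apart below percentile 2.5 or above 97.5. Chance would give this for 1.7 of 34 lists if members varied independently. Where members of a list vary together between cultures, more lists can stand apart without any effect of the inhibitor. With members detected on 1 array only set at their bound, list medians moved by at most 0.062. Lists share some genes. The genes named are the 12 highest and 12 lowest among those detected on both arrays, whose direction in the authors' normalized values is the same by construction. To these were added up to 5 per direction detected on 1 array only, the 3 highest and 3 lowest members of every list that stood apart and of the lists for ERK output, immediate early genes, EGF family, RAS-RAF-MEK-ERK cascade, p53, cell cycle and apoptosis, and a short list of pathway genes. Other genes named in the text were chosen after their values were seen.

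After the data were examined, detected genes with an annotated position (10420 genes) were scanned along each chromosome in windows of 15 neighbours. Window medians were set against 1000 random reorderings of the genes. The size rule, the list percentile and the scan were tested on simulated data made from the vehicle intensities of 6383 genes well above background, with log2 noise set at an SD of 0.2. Dim genes were not simulated. Changes of 2.5 on the log2 scale of the true signal passed the 2-fold rule in 100.0% of simulated increases and 81.6% of decreases. Changes of 1.5 passed in 82.0% and 44.0%. Every simulated gene started well above background with vehicle, so only decreases could end near background. The difference between directions follows from that setting and does not describe the measured genes. Of 100 unshifted lists 3 stood apart, with noise that was independent between genes. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.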

Results

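The series compared HCT116 colorectal carcinoma cells treated with SB590885, a small-molecule inhibitor of RAF kinases, with cells given vehicle. Per its title, the series addressed RAF inhibition across the genome in cultured cells. There was 1 array per condition. The values below therefore carry no replicate error, and each difference is one between these 2 arrays. On the vehicle array 15944 of 47318 probes (33.7%) were detected, and on the SB590885 array 16694 (35.3%). Named probes detected on at least 1 array covered 10430 genes. Of these, 9405 were measured by a probe detected on both arrays.

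The 2 profiles were close. Over genes detected on both arrays the log2 intensities correlated across genes with r = 0.984, where genes are not independent replicates, and the log2 ratios had an SD of 0.249. Of all detected genes, 97.3% differed by less than 1.5-fold. By the 2-fold rule 26 genes were higher and 14 lower after SB590885. With background correction these counts were 102 and 77, and with median centring in place of quantile normalization after that correction 96 and 82. The only repeated measurement within the arrays is that of different probes for 1 gene. Among 2295 genes with several detected probes, all probes had the same sign in 61.1%. This held for 71 of 85 such genes past 1.5-fold and for 8 of 9 past 2-fold. The exception past 2-fold was BLTP3B, at 1.20 and -0.04 on the log2 scale. Sizes repeated less well: the second probe passed 2-fold for 3 of the 9 genes, and was at 0.11 against 1.01 for RABGGTB and 0.33 against 1.04 for MTRF1L. The log2 ratios of a gene's 2 brightest probes correlated across genes with r = 0.494. They differed with an SD of 0.25, which carries the error of both probes. The SD of 0.249 above is that of single ratios over another set of genes, so the 2 are not like for like. With all probes of the same sign in only 61.1% of genes, small ratios often did not repeat between probes.

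In the deposited values the gene highest after SB590885 was SOX4, an SRY-box transcription factor (probe ILMN_1815745), which went from an intensity of 289.7 with vehicle to 1204.5, or 4.16-fold. This order depends on the background left in: with background correction ZBED2 (8.41-fold) and PRSS3 (6.65-fold) were above SOX4 (5.75-fold), and MKX was 5.12-fold higher. BAMBI, a pseudoreceptor that dampens TGF-beta signalling, was 3.88-fold higher (324.1 to 1258.4). PRSS3, a trypsinogen, was 3.48-fold higher as deposited and ZBED2, a zinc-finger transcription factor, 3.42-fold. PDE4B, a cyclic AMP phosphodiesterase, was 3.24-fold higher, with a second probe at a log2 ratio of 0.95. ADAM19, a membrane metalloprotease, was 3.24-fold higher. MKX, a homeobox factor, was 2.76-fold higher, and CD24, a surface glycoprotein, 2.49-fold. TMSB15A, a beta-thymosin, was 2.88-fold higher, but it has a near-identical copy, TMSB15B, that its probe may also bind. PRSS3 and CD24 likewise have close copies in the genome. Non-coding transcripts tied to small nucleolar RNAs were also among the highest 12: SNORA12 was 3.03-fold, SNHG8 2.97-fold and SNHG9 2.51-fold higher.

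The gene lowest after SB590885 was F3, which encodes tissue factor (probe ILMN_1797009) and went from 769.8 to 199.2, which is 3.86-fold lower, and its second probe had a log2 ratio of -1.77. CA2, a carbonic anhydrase, was 3.53-fold lower, with a second probe at -1.54. CYP24A1, the vitamin D 24-hydroxylase, was 3.06-fold lower. With background correction these 3 genes were 6.59-fold, 6.05-fold and 5.58-fold lower. NT5E, the ectonucleotidase CD73, was 2.23-fold lower, CPA4, a carboxypeptidase, 2.21-fold, and FGFBP1, a secreted carrier of fibroblast growth factors, 2.04-fold. PABIR2, on chromosome X, had a log2 ratio of -1.32. The remaining 5 of the 12 lowest were TFDP1 (2.48-fold), BORA (2.17-fold), ABCC4 (2.14-fold), TM9SF2 (2.12-fold) and STK24 (2.03-fold). The second probes of TFDP1 and ABCC4 had smaller log2 ratios of -0.88 and -0.55. All 5 lie on distal chromosome 13, where neighbouring genes were lower as a group. Without the genes of that run, 9 genes were at least 2-fold lower.

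**Figure D1:**
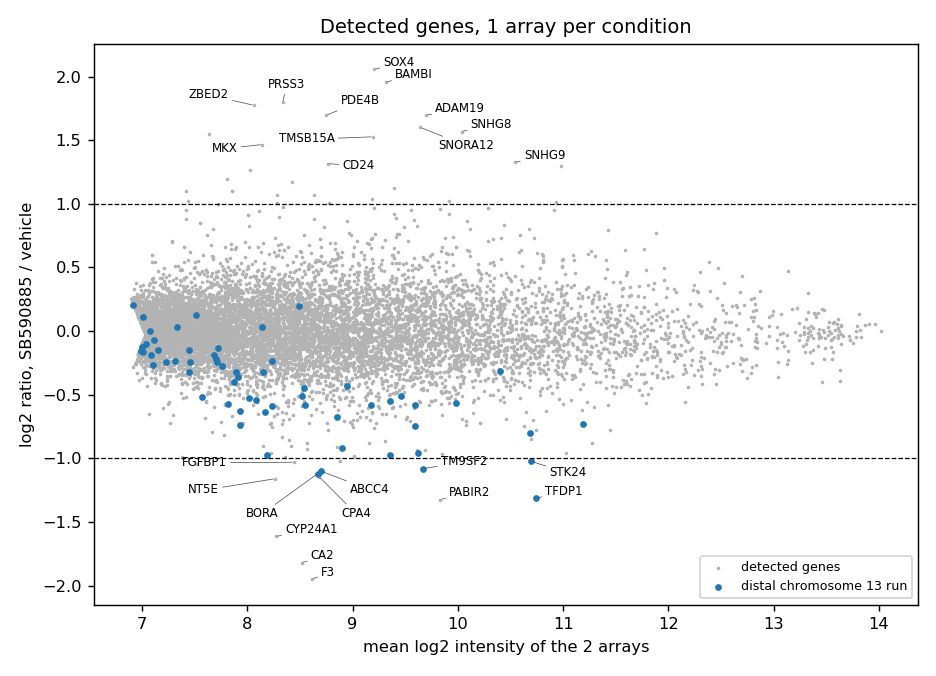
Log2 ratio of SB590885 over vehicle against mean log2 intensity of the 2 arrays for each of 10430 detected genes (grey), with genes of the distal chromosome 13 run in blue and dashed lines at 2-fold. The 12 highest and 12 lowest genes detected on both arrays are labelled; SOX4 and BAMBI are at the top and F3 and CA2 at the bottom.

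Of the detected genes, 1025 were detected on 1 array only, and those with the largest bounds were as follows. COX7B2, a testis-type cytochrome oxidase subunit, was not detected with vehicle and reached 340.7 after SB590885, at least 2.58-fold higher. RIMS2 (at least 1.90-fold), RGS17 (at least 1.86-fold), SYT1 (at least 1.80-fold) and STXBP6 (at least 1.76-fold) followed. RIMS2, SYT1 and STXBP6 encode proteins of regulated exocytosis, and RGS17 is a regulator of G-protein signalling. In the other direction, ZNF239 was at least 2.03-fold lower, EVA1A at least 1.80-fold, WNT16 at least 1.52-fold, PRKCQ-AS1 at least 1.51-fold and ENC1 at least 1.43-fold.

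Genes read out downstream of RAF, MEK and ERK differed little between the arrays. Of 20 detected members of the ERK output list, 8 were higher and 12 lower, and none reached 1.5-fold as deposited. DUSP6, the ERK phosphatase that is a standard readout of the pathway, was 1.29-fold higher (932.6 to 1202.9). PLAUR, the urokinase receptor, was 1.25-fold and the ETS factor ETV4 1.19-fold higher. ETV5, a related ETS factor, had a log2 ratio of -0.27, and the feedback inhibitors SPRED2, SPRY2 and SPRY4 had -0.25, -0.18 and -0.14. SPRY2 lies in the chromosome 13 run. CCND1 (cyclin D1) and MYC, at -0.14 and -0.06, were close to their vehicle levels. The list's median was -0.06, at percentile 18.6 of matched random lists, while its mean was 0.01. The list did not stand apart under any of 13 alternatives.

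Other lists of the same pathway gave similar values. Among 19 detected immediate early genes, which growth factors induce within an hour, only NR4A2 passed 1.5-fold as deposited (1.58-fold higher, 218.7 to 346.3). With background correction CCN1 also did, 1.72-fold lower. EGR1 had a log2 ratio of -0.39, SRF -0.47, KLF2 -0.44, CCN1 -0.44 and FOS -0.19, while IER2 (0.22) and FOSB (0.21) were higher. This list lay at percentile 52.5. Among EGF family genes, 6 of 7 detected members were higher, led by the ligand EREG at 1.47-fold (185.2 to 271.8; 1.98-fold with background correction), followed by ERRFI1 (1.11-fold) and TGFA (1.09-fold). EGFR, ERBB2 and ERBB3 had log2 ratios of 0.05, 0.05 and -0.05. The list's median was 0.08, at percentile 81.2. Of 14 detected components of the RAS-RAF-MEK-ERK cascade none passed 1.5-fold as deposited, and KSR2 did with background correction (1.79-fold lower). PTPN11 (-0.34), MAP2K2 (-0.32) and KSR2 (-0.31) were lowest and MAPK3 (0.26) and SHC1 (0.23) highest. NF1, next highest, was detected on 1 array only and lay at the limit of detection on both. MAP2K1 had 0.05 and ARAF -0.18.

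Targets of YAP and TEAD, the transcriptional arm of the Hippo pathway, were lower after SB590885, and theirs was the list farthest from its random lists. Of 11 detected members 10 were lower, 4 of them by at least 1.5-fold, and the median log2 ratio was -0.44. None of 10000 matched random lists had a median as low. F3 and NT5E, described above, were the lowest, followed by the receptor tyrosine kinase AXL, which was 1.87-fold lower (387.0 to 206.7). CCN2 (connective tissue growth factor), also at least 1.5-fold lower, went from 276.3 to 168.2, a log2 ratio of -0.72, and PTPN14 and CCN1 had -0.46 and -0.44. AJUBA, at -0.11, was close to its vehicle level. ARHGEF17, detected with vehicle only, was at least 1.04-fold lower, and AMOTL2, detected after SB590885 only, was at least 1.08-fold higher. With background correction the list's median was -0.81. The list stood apart under all 13 alternatives.

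**Figure D2:**
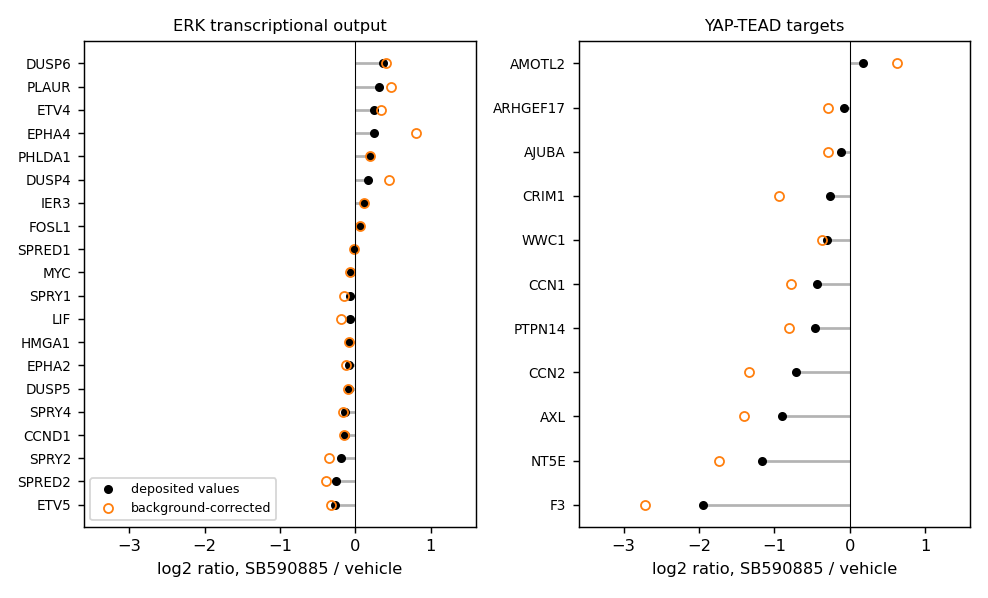
Log2 ratio of SB590885 over vehicle for each detected member of the ERK output list (left, 20 genes) and the YAP-TEAD list (right, 11 genes), from the deposited values (black) and after background correction (open orange); EPHA4, CRIM1, ARHGEF17 and AMOTL2 were detected on 1 array only, so their plotted ratios are not bounds. ERK output genes lie on both sides of 0, whereas 10 of 11 YAP-TEAD genes lie below it.

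Mitotic genes were slightly but broadly lower. Of 25 detected genes of the G2/M list, 21 were lower, none by 1.5-fold as deposited and CENPF by 1.52-fold with background correction. The median log2 ratio was -0.16, at percentile 0.92. CENPF, a kinetochore protein, had -0.50, the mitotic kinase AURKA -0.40 and the centromeric histone CENPA -0.36. UBE2C (0.34), CCNB1 (0.13) and CCNA2 (0.12) were higher. Replication-dependent histone genes also stood apart, with 7 of 11 lower, a median of -0.16 and percentile 0.90. H2BC5 was 1.65-fold lower (384.1 to 233.4), H2BC12 had a log2 ratio of -0.28 and H2AC6 was at least 1.08-fold lower, while H2AC20 was 1.41-fold higher, H4C14 1.19-fold and H4C8 at least 1.13-fold. Histone genes have near-identical copies, and with members detected on 1 array set at their bound this median was -0.11, which lies inside the range of the random lists. The random lists kept their own members at measured ratios, so that comparison is not like for like. With detection required on both arrays the histone list still stood apart, with a median of -0.16 at percentile 2.3. It did not stand apart in 2 of 13 alternatives. Genes of G1/S and DNA replication were split, with 12 of 23 higher and a percentile of 68.0. MCM7 was 1.32-fold higher, MCM5 1.18-fold and PCNA 1.12-fold, whereas CCNE1 (cyclin E1), TYMS and MCM10 had log2 ratios of -0.55, -0.44 and -0.43.

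Stress and cell death genes mostly stayed within 1.5-fold. Of 23 detected p53 targets, 10 were higher, at percentile 31.2. CDKN1A, which encodes the cell cycle inhibitor p21, had a log2 ratio of -0.30 (927.5 to 752.0), PPM1D -0.27 and TIGAR -0.25. BAX, the apoptosis effector, was 1.69-fold higher (150.6 to 254.4; 2.95-fold with background correction), ZMAT3 1.23-fold and TP53INP1 at least 1.25-fold. MDM2 was not detected on either array. Among 13 pro-apoptotic genes 9 were higher, with a median of 0.10 at percentile 94.1. After BAX came BIK (1.28-fold) and the death receptor TNFRSF10A (1.22-fold), and PMAIP1, which encodes the BH3-only protein NOXA, was lowest at -0.53, before DIABLO (-0.19) and APAF1 (-0.09). With background correction this list stood apart on the high side, at percentile 98.9. Of 7 anti-apoptotic genes none passed 1.5-fold, from CFLAR (-0.10), BCL2 (-0.07) and BIRC5 (-0.05) to MCL1 (0.05), BCL2L2 (0.07) and BCL2L1 (0.28). They lay at percentile 70.1.

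Of 34 ranked lists, 3 stood apart (YAP-TEAD, G2/M and histones), against 1.7 by chance if list members varied independently. The others included mesenchymal genes (median -0.14, percentile 5.12), which stood apart with background correction (-0.46, 0.29), splicing factors (-0.11, 4.61) and ER chaperones (-0.11, 8.33) on the low side, and MYC targets with ribosome biogenesis (0.06, 89.8), autophagy and lysosome (0.04, 79.4) and NF-kB targets (0.06, 78.9) on the high side. Lists of the ATF4 response (-0.07, 14.8), HIF targets (-0.08, 12.9), cholesterol biosynthesis (-0.07, 19.1), Wnt targets (-0.07, 16.6), interferon-stimulated genes (-0.05, 18.2), TGF-beta targets (-0.05, 22.6), metallothioneins (-0.08, 22.9) and respiratory chain subunits (-0.06, 24.8) lay within the range of random lists. So did housekeeping genes (-0.06, 34.7), epithelial junction genes (-0.01, 50.4), heat shock genes (-0.02, 61.0), NRF2 targets (0.01, 64.1), glycolysis (percentile 68.5), the proteasome (-0.01, 68.5), ribosomal proteins (-0.02, 69.9), DNA repair (0.02, 71.4) and fatty acid synthesis (0.04, 73.5). Markers of other cell types were mostly below detection on these arrays: 2 of 13 leukocyte genes, 3 of 12 stromal genes and 2 of 9 endothelial and erythroid genes with a named probe were detected, none of them different by 1.5-fold as deposited. Intestinal differentiation markers were detected for 4 of 19 genes, of which CA2 alone passed 1.5-fold.

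**Figure D3:**
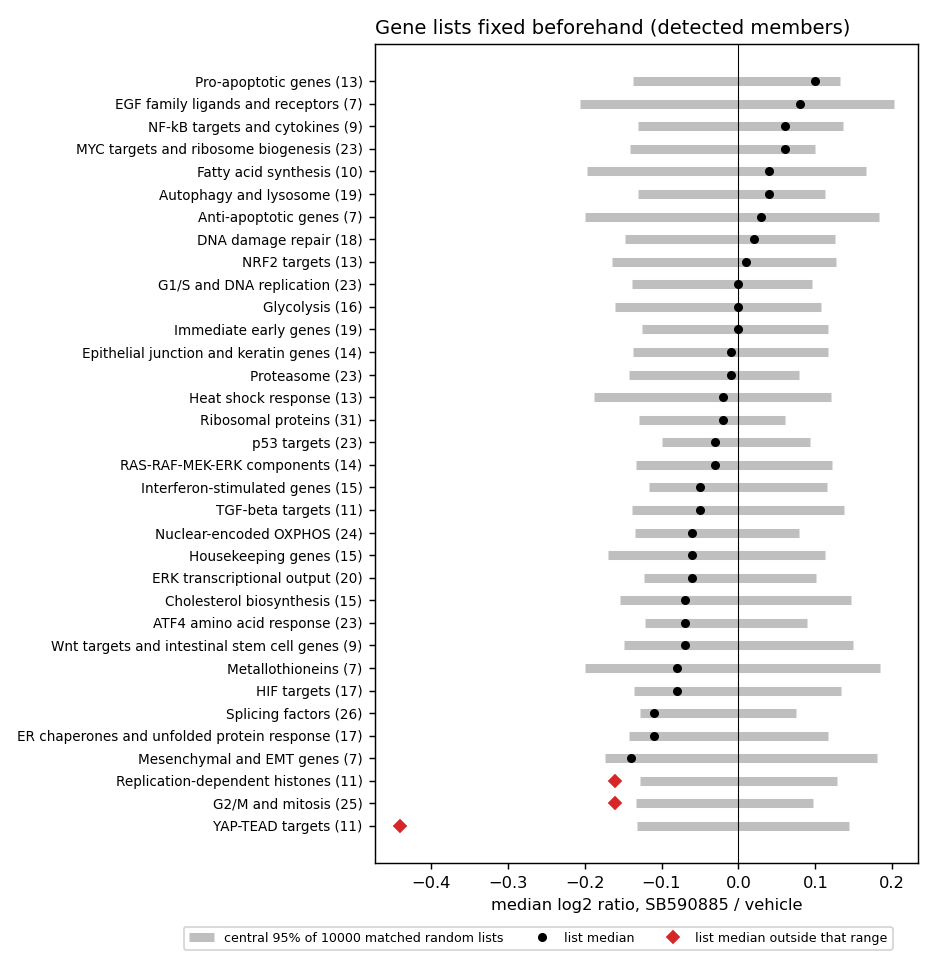
Median log2 ratio of SB590885 over vehicle for each of 34 gene lists (number of detected members in brackets), with grey bars for the range of 10000 random lists matched on expression outside which a list was said to stand apart. Red diamonds mark the 3 lists outside it, of which the YAP-TEAD list at -0.44 lies farthest out.

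By gene position, 1 part of the genome stood out. From OR7E156P to CHAMP1 on distal chromosome 13, 54 of 61 detected genes (88.5%) were lower after SB590885, against 49.9% of genes elsewhere. Their median log2 ratio was -0.40, and -0.64 with background correction, which is 1.56-fold lower. The run was taken from the first to the last gene of the windows whose medians lay below every reordering. Its genes were thus chosen by these same ratios, so a high share lower and a low median follow in part from that choice. The run held 17 of the 121 genes that were at least 1.5-fold lower and 5 of the 14 at least 2-fold lower. Members chosen after their values were seen are TFDP1, a partner of E2F factors, LAMP1, a lysosomal membrane protein (-0.80), the DNA repair nuclease ERCC5 (-0.73) and CDC16, a subunit of the anaphase-promoting complex (-0.75). The lowest median of 15 neighbouring genes was -0.53, whereas the lowest in 1000 random reorderings was -0.35. The 20 detected genes just before the run, from TRIM13 to TDRD3, had a median of 0.23, and 3 of them were lower. Of these 3, DIAPH3 (-0.81) and TDRD3 (-0.24) lie directly next to the run, and VPS36 had -0.02. The first gene of the run is therefore the edge of a window and not a measured border. On every other chromosome the window medians stayed between the lowest and highest of the reorderings. The next lowest was on chromosome X (-0.32). The scan was added after the values were seen.

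**Figure D4:**
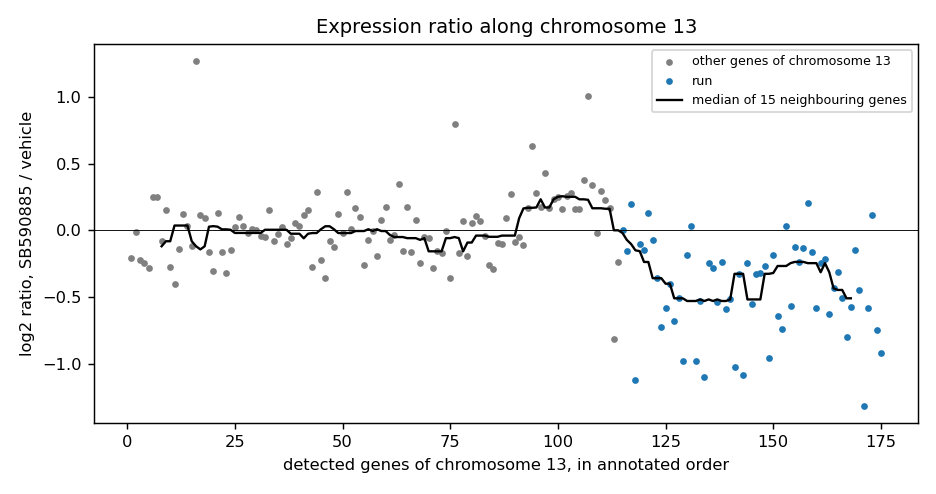
Log2 ratio of SB590885 over vehicle for the detected genes of chromosome 13 in annotated order, with genes of the run in blue and the median of 15 neighbouring genes as a line. The line stays near 0, is above it for the genes just before the run, and is negative through the run as far as GRTP1, the last gene with a full window.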

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

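Probes without a gene name here lie outside the gene counts above, and some of them passed the same 2-fold rule. Among 3012 such probes detected on both arrays, 3 were at least 2-fold higher after SB590885 and 3 were at least 2-fold lower. The highest, ILMN_2414027, went from 647.1 to 1815.9, and the lowest, ILMN_1697733, from 657.2 to 296.4. No explanation was tested for these probes. With 1 array per condition, neither array was checked against others of its group.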

How the results depend on the processing

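Background correction decided the counts. With neqc at offsets of 50, 16 and 1, 46, 102 and 197 genes were at least 2-fold higher and 38, 77 and 174 lower, against 26 and 14 as deposited. With neqc's correction and median centring they were 96 and 82. The offset of 16 and the removal of the chromosome 13 run were added after seeing the data. Without the genes of that run 9 genes were at least 2-fold lower, and a 1.5-fold rule gave 157 higher and 121 lower. Other detection filters, the probe rule and the +16 offset without correction left both counts within 1.5 times. The series matrix holds the main values again, so it could not move anything. The ERK list's median changed to 0.01 when the mean was used, and stayed from -0.08 to -0.06 otherwise. The number of lists standing apart was 5 with neqc at offsets of 16 and 1, with median centring, and with means, and 2 to 4 otherwise. The YAP-TEAD and G2/M lists were among them under all 13 alternatives and the histones under 11. The mesenchymal list joined in 4, the pro-apoptotic list in 3, and splicing factors, proteasome and housekeeping genes in 1 each; the cause was not tested. No named gene past 1.5-fold and no list that stood apart changed direction. Probe agreement stayed close to its main value under both alternatives. The median of the chromosome 13 run moved in 6 of 10 alternatives, all added after seeing the data, from -0.40 to between -0.76 and -0.36. No paired analysis was possible because each condition has 1 array, and none could be left out. Dim genes are limited most: with a background of about 112.5 left in, a gene near the lowest detected intensity of 132.2 could not pass the 2-fold rule downwards even if lost completely. Brighter genes were held back too, since a gene not detected after SB590885 was counted at 129.8. EVA1A, at 234.2 with vehicle, was thus at least 1.80-fold lower, whereas its measured ratio with background correction was 5.91-fold lower.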

Other observations

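All tests of this part were chosen after the patterns and the values of their genes were seen. The SNHG genes, named as host genes of small nucleolar RNAs, were mostly higher after SB590885, and no list had covered them. Of 14 detected SNHG genes 12 were higher, with a median log2 ratio of 0.20, and 10 of 10000 matched random lists had a median as high. SNHG6 (0.77), SNHG7 (0.59) and SNHG15 (0.34) followed SNHG8 and SNHG9, whereas SNHG10 and SNHG11 had -0.03 and -0.04. Probes named for small nucleolar and Cajal body RNAs themselves (SNORA, SNORD and SCARNA, 118 genes) were higher for 86, with a median of 0.08. Such short RNAs largely lack poly(A) tails, so these probes may bind host transcripts, which was not tested. The 2 genes past 2-fold do not carry the class alone, since the other 12 lay at percentile 99.8. Whether short transcripts as such had a greater yield stays open: most ribosomal protein probes lie near the array's ceiling, and the 6 genes no brighter than the SNHG genes had a median of 0.11. A difference in transcription or decay of these RNAs, caused by the inhibitor or by any other difference between the cultures, stays open and untested.

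Genes of the distal chromosome 13 run were lower together. When genes were reordered freely, as unrelated responses of single genes would fall, the lowest window was -0.35, against -0.53 observed. When they were reordered only among genes of like expression, which keeps any intensity trend, it was also -0.35, so neither accounts for the run. Unequal DNA copy number, for example through a different mix of subclones, is a candidate explanation that these arrays do not decide. In the run 16 of 17 second probes (94.1%) were lower. Second probes of genes elsewhere with a first probe as low were lower in 75.9% on average. The upper limit of such draws, set at the same percentile as for the lists, was also 94.1%. A second probe shows whether a lower mRNA level repeats and not what lowered it, so these shares cannot bear on copy number. DNA was not measured, and a regional effect of the inhibitor on transcription stays open and untested.

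The YAP-TEAD list was lower beyond its strongest members. Without F3, NT5E and AXL the other 8 members had a median of -0.28, at percentile 0.0 (0 of 10000 random lists as low), so 3 genes do not account for it. Over 6 other background corrections and normalizations, of which the series matrix holds identical values, the highest percentile was also 0.0. All 6 start from the same already normalized intensities, so they cannot exclude an intensity trend or an effect of the original normalization. Whether the inhibitor lowers these genes, as a hypothesis, or the cultures differed in density, to which these genes are known to respond, was not tested: the labels give 1 confluence for both cultures and no measurement of it.

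On chromosome X the window of 15 neighbouring genes around C1GALT1C1 had a median of -0.32, short of the lowest reordered window, with OCRL at -0.78 and LAMP2 at -0.49. With background correction, chromosome 6 also gave a window beyond the reorderings (0.67, where the highest reordered window had 0.63), near MTHFD1L and AKAP12.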
